A study of Mus musculus with 6 samples.

How the data were processed

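Gene expression was measured in hearts of 8-week-old C57/B6 mice on 1-colour (Cy3) Agilent mouse arrays. Per the labels, 3 hearts came from mice with floxed PHD2 and PHD3 alleles and no Cre, and 3 from mice with the same alleles and Cre, and the replicates are biological. The labels do not name the Cre driver, an inducer, the deleted exons or the sex of the mice. For the RNA they give a column kit used on hearts in one place and a blood RNA kit with globin depletion in another, which was not resolved here. All 6 arrays lay on 1 slide and were read in 1 scan, with the control arrays in a different column of positions from the KO-labelled arrays, so a slide block could not be fitted. The main comparison was of KO-labelled with control hearts.

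The deposited scanner files give the brightness of each spot as intensity values on a linear scale, made per the file headers with Agilent Feature Extraction 11.0.1.1, which subtracted the background and removed spatial trends without scaling between arrays. Other columns of these deposited files hold flags for spots well above background, saturated or outlying, also set by that software per the file headers. The deposited value table holds log2 values, for which the submitters' notes name Feature Extraction and R 3.1.3, and the authors' normalization is not given in the sources used here. Checked against the scanner files, 94.9% of its differences between arrays equalled the scanner's log2 differences plus 1 constant per array within 0.001. In 94.2% of its rows the median was 0 within 0.001, and it held only probes well above background on at least 4 arrays. Its column medians were 0.09, -0.02 and 0.07 for the control arrays and -0.04, -0.05 and -0.02 for the KO-labelled arrays, and why the remaining values differ stays unknown. The values of this table served only as an alternative source.

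From the scanner files, log2 of the processed signal was taken, spots flagged as outliers were left out, repeated spots of a probe were averaged, and the 75th percentile of each array was subtracted. Of 55681 distinct probes, 73 had only flagged spots on at least 1 array and were left out. Probes were named by matching RefSeq accessions to a gene table, which named 26551 and left 29057 without a symbol, and no probe positions were used. Probes well above background on every array of at least 1 group were kept, and each gene was represented by its probe with the highest mean. Of 4427 genes with more than 1 probe, 31 had probes that passed in opposite directions. The tests used limma 3.58.1 in R 4.3.3 with data.table, version 1.17.8: a linear model per gene with moderated variances, 2-sided, and Benjamini-Hochberg adjustment at 0.05. With 3 hearts against 3, an exact permutation test of a single gene cannot give a p below 0.1, so the calls rest on the variance pooled across genes. The arrays had 25778 to 28365 probes well above background and a 75th percentile signal of 147 to 235. Signals of arrays within the control group correlated across genes at 0.983 to 0.993, within the KO-labelled group at 0.976 to 0.987 and between groups at 0.922 to 0.970, and genes are not independent replicates.

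For a gene not well above background on any array of a group, the fold is given against a floor. Each array of that group was given at least the lowest signal that any probe well above background had on it. That floor lay so low that it changed these folds little or not at all. They are therefore estimates from signal near background and not lower bounds. List medians did not move (0 on the log2 scale) with such genes set against the floor, in the 3 lists that had any. Each of these lists had only 1 such gene, so this could not show whether dim genes matter to the lists. Gene lists were tested with camera, with a preset correlation of 0.01 between genes and at least 5 measured members, also with an estimated correlation and with fry, adjusted over the lists. Of 822 list genes, 812 had a probe. The lists covered HIF targets, oxygen sensing, thyroid hormone, calcium handling, beta-adrenergic signalling, the fetal programme, sarcomere, ion channels, energy metabolism, matrix, markers of 14 cell types, stress, inflammation, clock, cell cycle, cell death and sex-linked genes. Genes were named by a fixed rule. It took Egln1, Egln3, Egln2, Pln, Thra and Atp2a2, and the 10 largest rises and 10 largest falls among genes with a symbol that passed without overlap between groups, predicted genes and clones left out. From each list it took up to 4 passing members with the smallest p, or the 2 with the smallest p where fewer than 2 passed.

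The alternatives tried were normexp background correction (offset 50), quantile, median and cyclic loess scaling, the deposited value table, other filters on dim probes, every probe or the mean of a gene's probes, variance with trend and robust fitting, array weights, the replicate block, leaving out each heart, other thresholds and a plain test per gene. Normexp used median spot signals because the files read here hold no mean signals. Scaling on 7 E1A spike-in probes, array weights fitted gene by gene and named genes alone were added after the data were seen. The steps were tested on simulated data with 20027 genes of which 200 were changed. At 1.5-fold 0% were recovered by limma, at 2-fold 44.8% and at 4-fold 77.3%, and 8 of 89 calls were on unchanged genes. With the changes of the called genes put in, 85.5% were recovered and 2.89% of calls were on unchanged genes. These were the fitted changes of genes that had already passed, with no change in all others, which favours high recovery. The simulated genes varied independently of each other, unlike those on the arrays, so these shares need not hold for the real calls.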

Results

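RNA from whole hearts of 8-week-old C57/B6 mice was hybridised in 1 colour to Agilent mouse gene expression arrays, 1 array per heart. Per the labels, 3 hearts came from control mice that carried floxed alleles of PHD2 and PHD3 and no Cre recombinase, and 3 from mice with the same floxed alleles and Cre, here called the KO-labelled hearts. PHD2 and PHD3 are the prolyl hydroxylases that mark the hypoxia-inducible factors (HIF) for destruction when oxygen is present, and their genes are Egln1 and Egln3. The series title names the question as how these enzymes act through thyroid hormone receptor alpha on phospholamban, a brake on calcium uptake in cardiomyocytes. Each array held 55681 distinct gene probes, of which 55608 were kept. Of these 46.4% to 51.0% lay well above background and 0 were saturated. The number of arrays, 3 per group, limits the precision of every value.

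The targeted genes moved in opposite directions. Egln1 (NM_053207) had a log2 signal relative to the array's 75th percentile of 1.22 ± 0.21 (SD, n = 3) in control hearts and -0.01 ± 0.34 (SD, n = 3) in KO-labelled hearts, a 2.35-fold fall (log2 difference -1.23 ± 0.21 SE, adjusted p = 0.00654). Per heart, its signal was 1.27, 1.39 and 0.99 in the controls and -0.39, 0.29 and 0.06 in the KO-labelled hearts. Egln3 (NM_028133) had 2.57 ± 0.13 (SD, n = 3) in control and 4.54 ± 0.27 (SD, n = 3) in KO-labelled hearts, a 3.93-fold rise (log2 difference 1.98 ± 0.17 SE, adjusted p = 0.00166). Per heart, it was 2.57, 2.44 and 2.69 in the controls and 4.24, 4.62 and 4.77 in the KO-labelled hearts. The other Egln3 probe also lay higher, by 1.87 on the log2 scale. Egln3 therefore went against the label at face value, and the groups are called by their labels throughout. Egln3 is itself a HIF target, the labels do not name the deleted exons, and where the probes lie relative to the deleted part is not known. Egln2, the gene of the related hydroxylase PHD1, did not pass (log2 difference -0.27 ± 0.13 SE, adjusted p = 0.14). Among 11 oxygen sensing genes, Egln3 rose and 3 fell, which were Egln1, the factor-inhibiting hydroxylase Hif1an (log2 difference -0.57) and Epas1, which encodes HIF-2 alpha (log2 difference -1.11), and the counts were the same when adjusted over the list alone. That list as a whole did not pass (adjusted p = 0.587). Hif1an did not pass with the arrays set level on E1A spike-in probes (adjusted p = 0.145), nor Epas1 without control replicate 1 (adjusted p = 0.063).

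**Figure D1:**
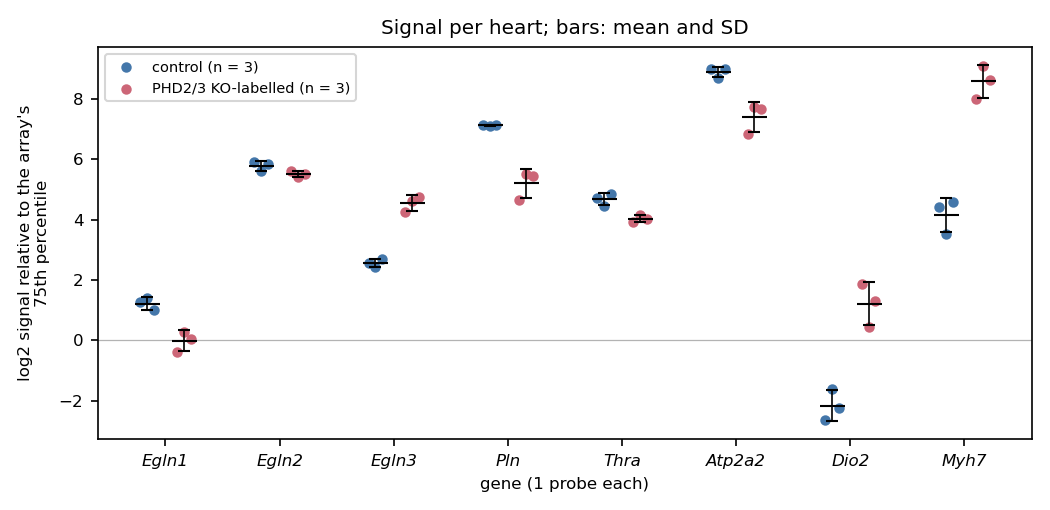
Signal per heart for 8 genes, as log2 signal relative to the array's 75th percentile (vertical axis) for 3 control (blue) and 3 KO-labelled hearts (red), with the group mean and SD as black bars. Egln1, Pln, Thra and Atp2a2 lay lower and Egln3, Dio2 and Myh7 higher in all 3 KO-labelled hearts than in any control heart, Egln2 overlapped, and levels of different genes are not comparable because each has its own probe.

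The KO-labelled hearts differed from the controls in a large part of the measured transcriptome. Among the lists that passed with a preset correlation between genes and not with an estimated one, 30 of 35 genes of fatty acid oxidation, 26 of 30 of the citric acid cycle, 52 of 53 of the respiratory chain, 16 of 26 of the sarcomere and 14 of 22 of ion channels fell. In further lists of that kind, 31 of 36 genes of the extracellular matrix, 22 of 23 of the cell cycle, 12 of 24 of the fetal cardiac programme, 12 of 24 of glycolysis and glucose uptake and 14 of 21 of the interferon response rose. Phospholamban, Pln, fell 3.79-fold and the slow myosin heavy chain Myh7 rose 21.4-fold. In limma's moderated test with Benjamini-Hochberg adjustment, 7818 of 20027 genes and unnamed features passed an adjusted p of 0.05 (39.0%), 3216 higher and 4602 lower. Among the 13198 with a gene symbol, 2526 were higher and 3019 lower, and 408 rose and 131 fell by at least 4-fold. The groups did not overlap for 55.8% of all genes and features tested, where chance gives 10%. The count depended on the processing. It was 13713 with array weights, 12703 with array weights gene by gene, 4345 without a filter on dim probes and 4854 with the replicate block. It also fell without some hearts: without control replicate 1 it was 3962, without control replicate 3 it was 4121, and without KO-labelled replicate 3 it was 5140. The split depended on scaling: 41.1% of the changed genes and features were higher as scaled here, 55.3% after cyclic loess and 59.8% with spike-in scaling, which was chosen after the data were seen. These scalings moved the median log2 difference of all genes, -0.11 as scaled here, by 0.14 and 0.24. Each gene named below as having risen or fallen had all 3 KO-labelled hearts on the same side of all 3 control hearts.

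Of 43 gene lists fixed before the data were examined, 41 had enough measured members for the list test, and 22 passed with a preset correlation between genes, 13 higher and 9 lower. With a correlation estimated from the 6 arrays, camera called 0 lists, with 2 at an unadjusted p of 0.05. The rotation test fry called 20 lists for a shift to 1 side and 35 for change in either direction. Unlike camera, fry asks whether a list's own members changed, not whether they changed more than other genes. Since 39.0% of all genes and features passed, the 35 calls say little about any single list. List members named outside the fixed rule, to help complete counts of up to 5, were chosen after their values were seen. Of these 32 genes, 8 (Pfkm, Fkbp1b, Hopx, Pdk1, Pdk3, Tagln, Cspg4 and Herpud1) passed under every alternative run. The other 24 did not pass under at least 1, with Timp3 (adjusted p up to 0.345), Rora (up to 0.320) and Itgam (up to 0.269) furthest from it. Among called genes within the rule, Krt18 did not pass under 11 of 21 alternatives, Hba-a2 under 10, Jund and Plvap under 9, Pgf under 7, Thra, Aplnr, Flt1, Irx4 and S100b under 6, and Cd3d under 8 of 20. Normexp, which lowers differences of dim genes, gave log2 differences of 2.28 for Dio2, 1.78 for Fmod, 1.19 for Col15a1, 2.69 for Col8a1, 1.95 for Egr2, 1.83 for Cxcl10, 3.43 for Cilp, 0.96 for Arntl, 0.66 for Mthfd2, 0.42 for Trp53, 0.33 for Apaf1 and 0.96 for Napsa, in place of the values below. Of the 22 lists, fry did not call the fibroblast, macrophage, lymphocyte, erythroid, inflammation and immediate early lists.

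The largest changes included genes outside the usual cardiac repertoire, and the size of many of them depended on how background was subtracted. Esr1, the gene of estrogen receptor alpha, was 1318-fold higher in KO-labelled hearts against the floor signal by 1 of its 3 probes (adjusted p = 0.00125). This probe was well above background on 3 of 3 KO-labelled arrays and 0 of 3 control arrays. The other 2 Esr1 probes were not well above background on any array. Crct1, an epidermal differentiation gene, was 117-fold higher against the floor (adjusted p = 0.00604). Among the other genes with the largest rises, Sprr1a, a cornified envelope gene, had a log2 difference of 7.69 ± 1.03 SE, Cthrc1, which encodes a secreted protein of remodelling tissue, 5.82 ± 1.28 SE, and Tnnt3, the fast skeletal troponin T, 5.65 ± 0.43 SE. They were followed by the whey acidic protein family gene Wfdc18 (5.09), the latent TGF-beta binding protein gene Ltbp2 (5.08), the carbonic anhydrase gene Car9 (5.04), the mitochondrial protein gene Mgarp (4.87) and the collagen gene Col8a2 (4.82). Of these, Ltbp2 was well above background on all 3 control arrays, Tnnt3 and Col8a2 on 2, and Sprr1a, Cthrc1, Wfdc18, Car9 and Mgarp on 1. The folds given against the floor hold for the scanner's background subtraction only and are not lower bounds. With normexp background correction, all 10 rises passed at smaller log2 differences and in another order. They were 6.24 for Esr1, 5.02 for Sprr1a, 4.95 for Ltbp2, 3.99 for Tnnt3, 3.36 for Wfdc18, 3.01 for Car9, 2.98 for Crct1, 2.96 for Col8a2, 2.95 for Cthrc1 and 2.58 for Mgarp. In the deposited value table Cthrc1 had 2.63 and Wfdc18 2.64. Single hearts moved some of these values. Without control replicate 2, Sprr1a had 8.67, Cthrc1 7.44 and Wfdc18 5.80, and without control replicate 1, Sprr1a had 6.93 and Cthrc1 4.97. Cthrc1 had 5.06 without control replicate 3. Without KO-labelled replicate 1, Sprr1a had 6.86, Crct1 6.01 and Esr1 11.06, and Crct1 had 8.30 without KO-labelled replicate 2.

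The genes with large falls included metabolic and channel genes. Against the floor, the protease gene Prss55 was 22.8-fold lower, the medium-chain acyl-CoA synthetase gene Acsm5 18.7-fold and the lectin gene Clec18a 15.9-fold. Each was not well above background on any KO-labelled array. The potassium channel subunit gene Kcnv2 fell by 4.50 on the log2 scale, the cyclic nucleotide gated channel gene Cngb3 by 4.35, the carboxylesterase gene Ces1d by 4.11 and the fructose bisphosphatase gene Fbp2 by 3.64, and the protease inhibitor gene Timp4 (-3.56) and the ephrin gene Efnb3 (-3.51) followed. KO-labelled arrays with a signal well above background numbered 1 of 3 for Kcnv2 and Cngb3 and 2 of 3 for Fbp2. With normexp these genes passed with smaller falls, of -1.32 for Prss55, -1.28 for Acsm5, -1.59 for Clec18a, -2.02 for Kcnv2, -2.15 for Cngb3, -2.36 for Fbp2, -2.95 for Timp4, -3.18 for Efnb3 and -3.31 for Ces1d on the log2 scale. When the ranking was restricted, after the values were seen, to genes well above background on at least 1 array of each group, the rises it took in included the lysyl oxidase gene Lox (4.66), which was above background on 1 control array. Lox had 2.50 with normexp, 2.34 in the deposited table, 5.65 without control replicate 2 and 3.83 without control replicate 3. Among the falls it took in Cyp26b1, a retinoic acid hydroxylase gene (-3.41), the receptor gene Mrgprh (-3.39), the channel-interacting protein gene Kcnip2 (-3.35) and Ogdhl (-3.35), which encodes a form of oxoglutarate dehydrogenase. Mrgprh was above background on 1 KO-labelled array. With normexp these falls were -2.24, -1.21, -2.52 and -1.77. Without KO-labelled replicate 1 the falls were smaller, at -2.66 for Ces1d, -2.46 for Timp4, -2.65 for Fbp2, -2.76 for Efnb3, -3.60 for Kcnv2 and Cngb3, -3.10 for Clec18a and -2.60 for Mrgprh and Kcnip2. Without KO-labelled replicate 2 they were larger, at -5.31 for Ces1d, -4.51 for Timp4, -5.13 for Kcnv2, -5.03 for Cngb3 and -4.00 for Cyp26b1, and Mrgprh had -4.02 without KO-labelled replicate 3. Of the alternatives run, Ces1d and Timp4 did not pass under 7 of 21, Cthrc1 under 2 of 20 and Fbp2 under 1 of 20, with adjusted p of up to 0.102, 0.0797, 0.052 and 0.0504 without control replicate 1 or 3.

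HIF target genes rose in part. Of 24 measured genes of glycolysis and glucose uptake, 12 rose, 1 fell and 11 did not pass (15 and 2 adjusted over the list alone; list adjusted p = 7.86e-05, adjusted p = 0.472 with an estimated correlation). The lactate exporter gene Slc16a3 rose 17.3-fold, the phosphofructokinase gene Pfkp 3.28-fold, the glucose transporter gene Slc2a1 2.32-fold and the phosphoglycerate kinase gene Pgk1 1.97-fold. The member that fell was Pfkm, the muscle phosphofructokinase (log2 difference -1.53). Of 32 other HIF targets, 11 rose, 1 fell and 20 did not pass (11 and 1 adjusted over the list alone; list adjusted p = 0.000115, adjusted p = 0.388 with an estimated correlation), and the member that fell was the nuclear receptor gene Rora (-0.47). The rises included Car9, Lox and Egln3, and the synapse scaffold gene Ppfia4 rose 2.99-fold and the mitophagy receptor gene Bnip3 2.11-fold. The angiogenic factor Vegfa, named after its value was seen, did not pass (log2 difference 0.31 ± 0.17 SE, adjusted p = 0.183). Among 16 angiogenesis ligands, Igf1 rose 4.25-fold, 6 fell, including Cxcl12 (-1.13), Vegfb (-1.30) and Pgf (-1.01), and 9 did not pass (1 and 6 adjusted over the list alone). Cxcl12 did not pass with the mean of its probes (adjusted p = 0.0581) and Pgf did not with spike-in scaling (adjusted p = 0.116). That list did not pass (adjusted p = 0.739), and its median of 0.18 and mean of -0.01 had opposite signs.

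Thra, Pln and 10 of 18 genes known to rise with thyroid hormone fell. Thra (NM_178060) fell 1.57-fold (log2 difference -0.65 ± 0.15 SE, adjusted p = 0.0161), from 4.68 ± 0.20 to 4.03 ± 0.12 (SD, n = 3 each), and did not pass without control replicate 3 (adjusted p = 0.0627). The other Thra probe had -0.49. Adjusted over all probes with no filter, neither passed in limma (adjusted p = 0.0825 for the first and 0.142 for the other). Pln (NM_023129) fell from 7.13 ± 0.02 to 5.20 ± 0.49 (SD, n = 3 each; log2 difference -1.92 ± 0.24 SE, adjusted p = 0.00347). Of the 18 genes known to rise with thyroid hormone (T3) in heart, 10 fell, 0 rose and 8 did not pass (11 fell adjusted over the list alone; list adjusted p = 0.00956, adjusted p = 0.623 with an estimated correlation). Without the 11 members that other lists share, this list did not pass (adjusted p = 0.761). The falls included Atp2a2 (NM_009722), the calcium pump that phospholamban restrains (-1.48 ± 0.26 SE, adjusted p = 0.00735), the potassium channel gene Kcnd3 (-1.41), the insulin-regulated glucose transporter gene Slc2a4 (-1.64) and the calcium release channel gene Ryr2 (-0.83). The other Atp2a2 probe had -2.37. Of 9 genes known to fall with T3, Myh7 and Dio2, the activating deiodinase, rose (4.42 and 3.38), while Pln, Thra and the adenylyl cyclase gene Adcy6 (-0.99) fell and 4 did not pass (2 and 3 adjusted over the list alone; list adjusted p = 0.884). The median of that list was -0.15, its mean 0.49 and its test direction up, and its median turned to 0.09 with spike-in scaling.

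Among 17 receptors and coregulators of the thyroid axis, 2 rose, 6 fell and 9 did not pass (3 and 7 adjusted over the list alone; list adjusted p = 0.317). Dio2 rose 10.4-fold. Dio3, the inactivating deiodinase, was 6.58-fold higher against the floor, since it was not well above background on any control array. Dio3 did not pass with normexp (log2 difference 0.66, adjusted p = 0.104), and had 2.04 and 3.35 without KO-labelled replicates 1 and 2. The corepressor gene Ncor1 (-0.68), the transporter gene Slc16a10 (-0.68) and the retinoid receptor gene Rxrg (-1.59) fell, with a list median of -0.38 and a mean of 0.05. Ncor1 and Slc16a10 did not pass with spike-in scaling (adjusted p = 0.0767 and 0.0793). Of 30 calcium handling genes, 2 rose, 14 fell and 14 did not pass (3 and 16 adjusted over the list alone; list adjusted p = 0.0861). The falls included the genes of the dyad proteins Jph2 (-1.27), Asph (-1.70) and Trdn (-0.95), and the rises were Fkbp1b (1.66), a subunit of the calcium release channel complex, and Sri (0.69). The list passed without KO-labelled replicate 3 (adjusted p = 0.0358), and Trdn did not pass with the mean of its probes (adjusted p = 0.0568). Of 32 genes of beta-adrenergic signalling, 7 rose, 8 fell and 17 did not pass (7 and 9 adjusted over the list alone; list adjusted p = 0.829). Among them the protein kinase A subunit gene Prkar1a rose 2.00-fold and the G protein gene Gnb1 1.88-fold, and the subunit gene Prkar2a (-0.98) fell with Adcy6. The median of this list was -0.18 and became 0.06 with spike-in scaling.

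Part of the fetal programme genes rose, while most sarcomere and ion channel genes fell. Of 24 genes of the fetal and hypertrophy programme, 12 rose, 1 fell and 11 did not pass (12 and 1 adjusted over the list alone; list adjusted p = 0.000306, adjusted p = 0.507 with an estimated correlation). Besides Myh7, the matricellular protein gene Thbs4 rose 19.3-fold, the ubiquitin hydrolase gene Uchl1 8.49-fold and the LIM protein gene Fhl1 2.78-fold, while the homeodomain gene Hopx fell (-1.98). Of 26 sarcomere genes, 16 fell, 2 rose and 8 did not pass (16 and 2 adjusted over the list alone; list adjusted p = 0.00128, adjusted p = 0.623 with an estimated correlation). The falls included the muscle methyltransferase gene Smyd1 (-1.32), the cardiac troponin I gene Tnni3 (-1.57) and the Z-disc gene Ldb3 (-1.15), and the rises were the desmin gene Des (1.05) and the filamin gene Flnc (1.02). Of 22 ion channel genes, 14 fell, 1 rose and 7 did not pass (16 and 1 adjusted over the list alone; list adjusted p = 0.0008, adjusted p = 0.623 with an estimated correlation). Kcnk3 (-1.28), Kcnj11 (-1.53), Kcnd3 and Kcnj5 (-0.71), all potassium channel genes, were among the falls, and Kcnj5 did not pass with spike-in scaling (adjusted p = 0.0731).

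**Figure D2:**
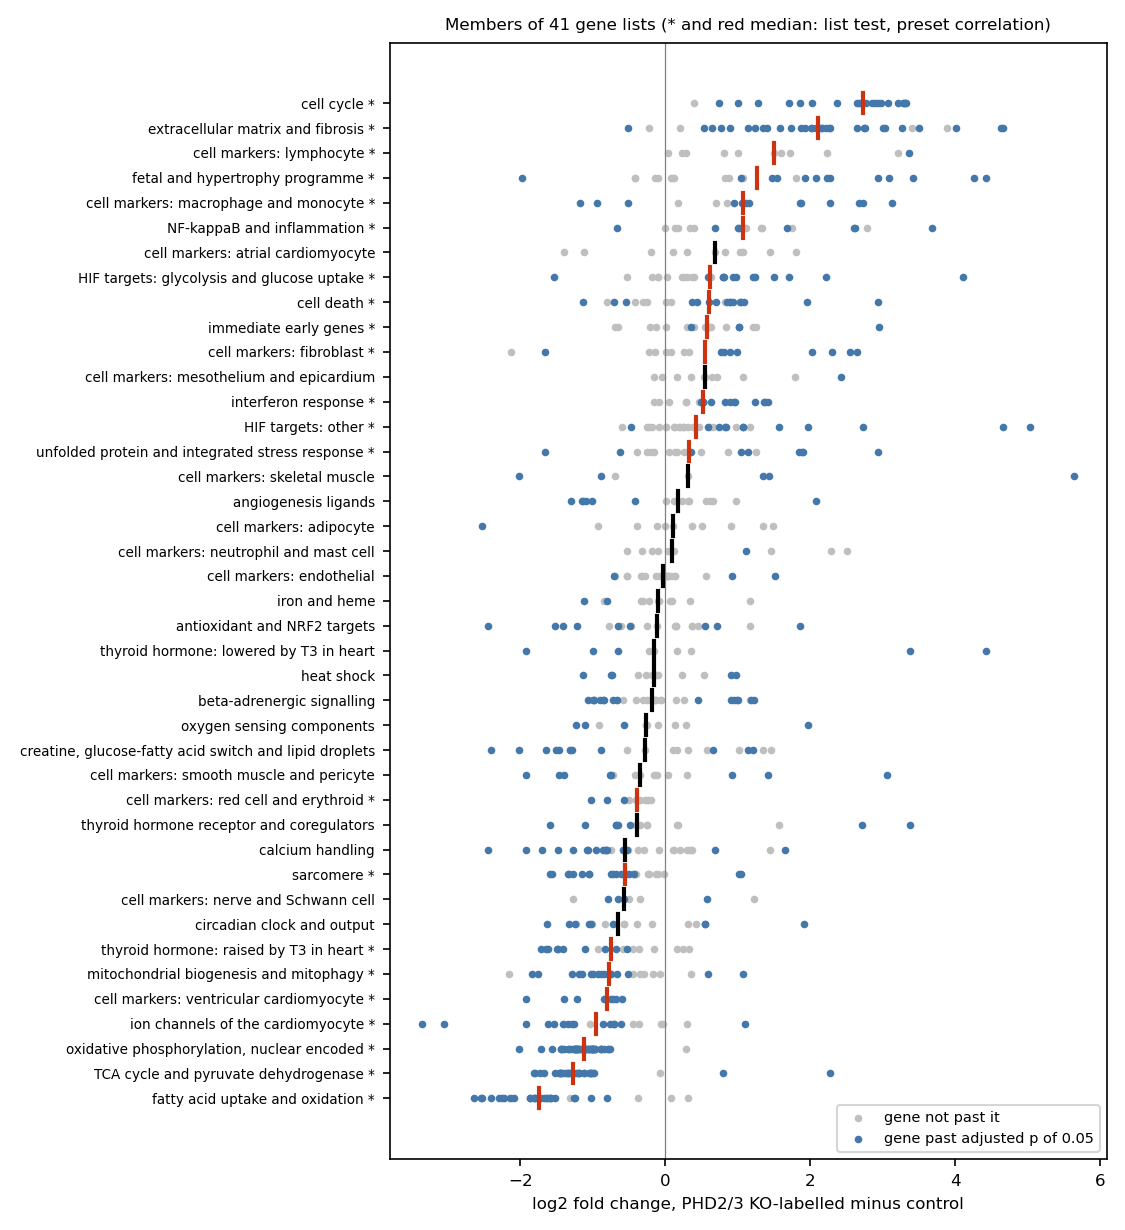
Log2 fold change of each measured member (points, horizontal axis) of 41 gene lists (vertical axis) between 3 KO-labelled and 3 control hearts, with the list's median as a vertical bar, red where the list test with a preset correlation passed an adjusted p of 0.05. Blue points passed an adjusted p of 0.05 over all genes and grey points did not. Cell cycle (median 2.73) and extracellular matrix (median 2.11) lay highest and fatty acid oxidation (median -1.75) lowest, and camera with an estimated correlation called 0 lists, 2 at an unadjusted p of 0.05, and fry called 20.

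Mitochondrial energy genes fell almost throughout. Of 53 nuclear genes of oxidative phosphorylation, 52 fell and 1 did not pass (52 fell and 1 rose adjusted over the list alone), with a median log2 difference of -1.12 (list adjusted p = 9.44e-14, adjusted p = 0.623 with an estimated correlation). The complex I gene Ndufa10 (-1.43), the complex II gene Sdhc (-1.34) and the complex III gene Uqcrfs1 (-1.44) were examples. Of 35 genes of fatty acid uptake and oxidation, 30 fell, 0 rose and 5 did not pass (33 and 1 adjusted over the list alone), with a median of -1.75 (list adjusted p = 4.22e-10, adjusted p = 0.623 with an estimated correlation). The thioesterase gene Acot1 fell 5.83-fold, the enoyl-CoA isomerase gene Ech1 6.22-fold, the carnitine acetyltransferase gene Crat 3.39-fold and the carnitine carrier gene Slc25a20 3.33-fold. Of 30 genes of the citric acid cycle and pyruvate dehydrogenase, 26 fell, 2 rose and 2 did not pass (27 and 2 adjusted over the list alone; list adjusted p = 4.17e-08, adjusted p = 0.623 with an estimated correlation). Dld (-1.39), Idh3b (-1.79), Sucla2 (-1.45) and Suclg1 (-1.35), all enzyme subunits of the cycle or its entry, fell, and Pdk1 (0.80) and Pdk3 (2.28), kinases that inhibit pyruvate dehydrogenase, rose.

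Of 25 genes of mitochondrial biogenesis and mitophagy, 16 fell, 2 rose and 7 did not pass (19 and 3 adjusted over the list alone; list adjusted p = 0.000753, adjusted p = 0.623 with an estimated correlation). The mitochondrial helicase gene Twnk (-1.14), the mitophagy kinase gene Pink1 (-1.75) and the fusion gene Mfn1 (-1.18) fell while Bnip3 and its relative Bnip3l (0.59) rose. In the list of creatine metabolism, substrate switching and lipid droplets, 3 of 21 genes rose, 8 fell and 10 did not pass (3 and 8 adjusted over the list alone; list adjusted p = 0.724). The mitochondrial creatine kinase gene Ckmt2 (-1.51), the lipid droplet gene Plin4 (-1.28) and Slc2a4 fell while Slc2a1, the brain creatine kinase gene Ckb (0.66) and the desaturase gene Scd2 (1.15) rose. Of 21 antioxidant genes, 3 rose, 6 fell and 12 did not pass (3 and 6 adjusted over the list alone; list adjusted p = 0.957), with the mitochondrial enzymes Prdx3 (-1.22) and Sod2 (-1.41) and the glutathione transferase gene Gstm1 (-1.52) lower and the glutathione peroxidase genes Gpx1 (0.71) and Gpx3 (1.87) and the extracellular superoxide dismutase gene Sod3 (0.55) higher. Of 13 genes of iron and heme, Alas1 (-1.13) and Fech (-0.80), both enzymes of heme synthesis, fell, 0 rose and 11 did not pass (2 fell adjusted over the list alone; list adjusted p = 0.595). The medians of these last 2 lists, -0.11 and -0.10, turned positive with cyclic loess and with spike-in scaling.

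Matrix and cell cycle genes rose almost throughout. Of 36 genes of extracellular matrix and fibrosis, 31 rose, 1 fell and 4 did not pass (32 and 1 adjusted over the list alone), with a median log2 difference of 2.11 (list adjusted p = 7.68e-14, adjusted p = 0.534 with an estimated correlation). The proteoglycan gene Fmod rose 6.70-fold, the collagen genes Col15a1 3.80-fold and Col8a1 11.3-fold, and the cartilage intermediate layer gene Cilp 16.2-fold, while the protease inhibitor gene Timp3 fell (-0.51). Control replicate 2 lay nearest to the KO-labelled hearts, with -33.9 on the first principal component against -77.5 and -70.1 in the other controls and 41.8 to 84.4 in the KO-labelled hearts. Its collagen Col1a1 signal was 5.62 against 3.88 and 4.22 in the other controls, and without it the matrix median was 2.50. Of 23 cell cycle genes, 22 rose, 0 fell and 1 did not pass, also adjusted over the list alone, with a median of 2.73 (list adjusted p = 3.43e-15, adjusted p = 0.472 with an estimated correlation). The proliferation marker Mki67 rose 7.25-fold and the replication licensing genes Mcm3 and Mcm6 3.62-fold and 3.29-fold. The list also holds the cell cycle inhibitor gene Cdkn1a, named after its value was seen (log2 difference 1.00, adjusted p = 0.0236). The mitotic kinase gene Cdk1 was 6.26-fold higher against the floor, since it was not well above background on any control array. It did not pass with normexp background correction (log2 difference 0.315, adjusted p = 0.08).

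Of 21 interferon response genes, 14 rose, 0 fell and 7 did not pass (15 rose adjusted over the list alone; list adjusted p = 8.34e-07, adjusted p = 0.472 with an estimated correlation), among them Isg15 (1.24), Ifi27l2a (1.38), Usp18 (0.96) and Oas1a (1.36). Of 18 genes of NF-kappaB and inflammation, 7 rose, 1 fell and 10 did not pass (7 and 1 adjusted over the list alone; list adjusted p = 0.00106, adjusted p = 0.623 with an estimated correlation). The chemokine genes Ccl5 (2.62) and Cxcl10 (2.60) and the pathway genes Relb (0.69) and Tnfaip3 (1.01) rose and the inhibitor gene Nfkbia fell (-0.66), and of these Relb, Cxcl10 and Tnfaip3 did not pass without control replicate 1 or 3 (adjusted p up to 0.0584, 0.0555 and 0.0866). Cxcl10 had 3.31 without control replicate 2. Of 23 cell death genes, 13 rose, 3 fell and 7 did not pass (14 and 5 adjusted over the list alone; list adjusted p = 0.00944, adjusted p = 0.472 with an estimated correlation). Trp53 (1.03), the necroptosis kinase gene Ripk3 (1.96) and the apoptosome gene Apaf1 (1.04) rose, and the death receptor gene Fas (-1.13), the survival gene Bcl2l1 (-0.70) and Diablo (-0.55) fell. Of 21 genes of the unfolded protein and integrated stress response, 7 rose, 2 fell and 12 did not pass (7 and 2 adjusted over the list alone; list adjusted p = 0.0112, adjusted p = 0.472 with an estimated correlation). The rises included the serine and one-carbon synthesis genes Psat1 (1.85), Mthfd2 (1.90) and Phgdh (1.88), and the chaperone gene Dnajb9 (-0.62) and Herpud1 (-1.66) fell. Dnajb9 did not pass with spike-in scaling (adjusted p = 0.107).

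Of 12 heat shock genes, 2 rose, 3 fell and 7 did not pass (2 and 3 adjusted over the list alone; list adjusted p = 0.739), with the mitochondrial chaperonin genes Hspd1 (-1.14) and Hspe1 (-0.75) and the cochaperone gene Bag3 (-0.73) lower and the chaperone genes Hspa1a (0.98) and Hsp90aa1 (0.91) higher, the last not without control replicate 1 (adjusted p = 0.0533). The median of that list, -0.16, was 0.08 with spike-in scaling and rounded to 0.00 with cyclic loess. Of 18 immediate early genes, 4 rose, 0 fell and 14 did not pass (2 rose adjusted over the list alone; list adjusted p = 0.0114, adjusted p = 0.623 with an estimated correlation), and these were the transcription factor genes Egr2 (2.95), Maff (1.02), Myc (1.01) and Jund (0.36). That list did not pass without KO-labelled replicate 2 (adjusted p = 0.0674) or with spike-in scaling (adjusted p = 0.066). Of 18 circadian genes, 3 rose, 6 fell and 9 did not pass (3 and 8 adjusted over the list alone; list adjusted p = 0.317), with Tef (-1.24) and Cry2 (-1.02) among the lower and Arntl (1.92, and 1.33 without KO-labelled replicate 1), Bhlhe41 (0.55) and Tspan4 (0.55) higher. Myc, Jund, Cry2 and Tspan4 did not pass under at least 1 alternative setting, with adjusted p of up to 0.0944, 0.175, 0.0536 and 0.0718. Of 3 measured sex-linked genes, too few for a list test, the Y-linked genes Ddx3y (-0.61) and Uty (-0.69) were present in every heart and fell, also adjusted over the list alone, but did not pass with spike-in scaling (adjusted p = 0.0594 and 0.112).

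Markers of other cell types did not move together. Of 17 macrophage and monocyte markers, 10 rose, 3 fell and 4 did not pass (11 and 3 adjusted over the list alone; list adjusted p = 0.000715, adjusted p = 0.623 with an estimated correlation), including Ms4a7 (3.13), Cx3cr1 (2.67), Ccr2 (2.73) and Adgre1 (1.88), while Cd163 (-0.95), Lyve1 (-1.18) and Itgam (-0.51) fell. Ccr2 was above background on 1 control array and had 1.19 with normexp. Of 16 fibroblast markers, 8 rose, 1 fell and 7 did not pass (8 and 2 adjusted over the list alone; list adjusted p = 0.0105, adjusted p = 0.623 with an estimated correlation), including the microfibril genes Mfap5 (2.30) and Mfap4 (2.55) and the collagen genes Col1a1 (2.64) and Col1a2 (2.02), while Gsn fell (-1.66). The fibroblast list did not pass without KO-labelled replicate 2 (adjusted p = 0.0557), with spike-in scaling (adjusted p = 0.0629) or without members shared with other lists (adjusted p = 0.111). All 8 measured ventricular cardiomyocyte markers fell, also adjusted over the list alone (list adjusted p = 0.00205, adjusted p = 0.623 with an estimated correlation), among them Pln, Mylk3 (-1.40), Tnni3k (-1.22) and Irx4 (-0.60), the last of which did not pass with spike-in scaling (adjusted p = 0.0852). Of 21 endothelial markers, Aplnr (0.93) and Plvap (1.52) rose, Flt1 (-0.70) fell and 18 did not pass (0 and 0 adjusted over the list alone, 6 at an unadjusted p of 0.05; list adjusted p = 0.9). The endothelial median was -0.03 and turned positive with quantile, cyclic loess and spike-in scaling, while its test direction was up. Flt1, Aplnr and Plvap did not pass without control replicate 1 or 3 (adjusted p up to 0.0866, 0.0744 and 0.114). Of 15 smooth muscle and pericyte markers, 3 rose, 5 fell and 7 did not pass (3 and 6 adjusted over the list alone; list adjusted p = 0.694), with the smooth muscle genes Cnn1 (3.06) and Tagln (1.42) and the pericyte gene Cspg4 (0.92) higher. Vtn (-1.46), Kcnj8 (-1.40), Abcc9 (-1.91) and Rgs5 (-0.75), all listed as pericyte markers, and Myh11 (-0.75), the smooth muscle myosin gene, were lower. Abcc9 is also in the list of cardiomyocyte ion channels, so its fall need not come from pericytes.

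Of 11 lymphocyte markers, Cd3d rose (3.37) and 10, including Cd5 (log2 difference 1.72, adjusted p = 0.0647), did not pass (0 adjusted over the list alone; list adjusted p = 0.0114, adjusted p = 0.625 with an estimated correlation). Cd5 had 2.12 and 0.94 without KO-labelled replicates 1 and 2, and 0.59 with normexp. Cd3d was above background on 1 control array, and its signal in the KO-labelled hearts was -1.88, 1.47 and -1.64. Its log2 difference ranged from 1.20, with normexp, to 3.99, without control replicate 2, and was 2.29 without KO-labelled replicate 2. It did not pass under 8 of 20 alternatives (adjusted p up to 0.124, without control replicate 1), and the list did not with only probes above background on all arrays (adjusted p = 0.102), array weights (0.242) or those gene by gene (0.125). Of 11 neutrophil and mast cell markers, Kit rose (1.11), and the others, Elane (log2 difference -0.53, adjusted p = 0.0889) among them, did not pass (1 adjusted over the list alone; list adjusted p = 0.317). Of 12 erythroid markers, Sptb (-1.03), Fech and Hba-a2 (-0.57) fell and 9 did not pass (2 fell adjusted over the list alone; list adjusted p = 0.0415, adjusted p = 0.623 with an estimated correlation). Hba-a2, an alpha globin gene that shares sequence with its neighbouring copy, had an adjusted p of 0.763 after quantile normalization, and the erythroid list did not pass with normexp (adjusted p = 0.0586), quantile (0.176), cyclic loess (0.0576) or spike-in scaling (0.0584), with unshared members (0.0872), or without control replicate 1 (0.121) or KO-labelled replicate 3 (0.0957). Of 7 skeletal muscle markers, Tnnt3, Mybpc2 (1.35) and Tnni2 (1.44) rose, Ckm (-2.01) and Pvalb (-0.88) fell and 2 did not pass (3 and 2 adjusted over the list alone; list adjusted p = 0.317). Tnni2 did not pass without control replicate 3 (adjusted p = 0.0808), and Ckm is also in the list of creatine metabolism. Of 9 nerve and Schwann cell markers, S100b rose (0.58), 3 fell, including Th (-0.79) and Snap25 (-0.64), and 5 did not pass (1 and 3 adjusted over the list alone; list adjusted p = 0.283). S100b and Snap25 did not pass under at least 1 alternative setting, with adjusted p of up to 0.0847 and 0.0505.

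Markers of fat, lung, atrium and mesothelium varied between hearts of both groups. The mean log2 signal of 11 adipocyte markers lay 1.27 above the control mean in control replicate 3 and 2.81 above it in KO-labelled replicate 2, and that of 4 lung markers lay 2.37 and 3.43 above it in the same 2 hearts. Lymphocyte markers were highest in KO-labelled replicate 2 (2.93), against 0.78 and 0.66 in the other KO-labelled hearts. Atrial markers ranged from -2.06 to 1.70 among control hearts and from -1.13 to 1.73 among KO-labelled hearts, and 11 mesothelial and epicardial markers were 1.63 above the control mean in control replicate 2. Of these lists, 0 of 11 atrial genes passed in limma (1 at an unadjusted p of 0.05), with Kcnj3 (log2 difference -1.40, adjusted p = 0.0515) and Nppa (log2 difference 1.80, adjusted p = 0.0994) nearest (list adjusted p = 0.587). Nppa had 1.00 without control replicate 1 and 2.65 without control replicate 2. Among 11 adipocyte genes only the triglyceride synthesis gene Dgat2 fell (-2.53) and 10, including Cidea (log2 difference 0.51, adjusted p = 0.0813), did not pass (list adjusted p = 0.761). Dgat2 did not pass without control replicate 1 (adjusted p = 0.061) and had -1.82 without KO-labelled replicate 1. Among 11 mesothelial and epicardial genes only Krt18 rose (2.43), and 10, including Aldh1a2 (log2 difference 1.79, adjusted p = 0.0594), did not pass (list adjusted p = 0.129). Aldh1a2 had 1.39 without control replicate 1 and 2.48 without control replicate 2. Krt18 did not pass under 11 of 21 alternatives (adjusted p up to 0.132, without control replicate 3), with 1.79 without control replicate 1 and 3.31 without control replicate 2. Without control replicate 2 the mesothelial list passed (adjusted p = 6.13e-05). Among 4 lung genes, too few for a list test, only the protease gene Napsa rose (2.50), and Lamp3 did not pass (log2 difference -0.24, adjusted p = 0.14; log2 difference 0.01 with spike-in scaling). Adjusted over the list alone, Dgat2 and Napsa passed and no atrial or mesothelial gene did.

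**Figure D3:**
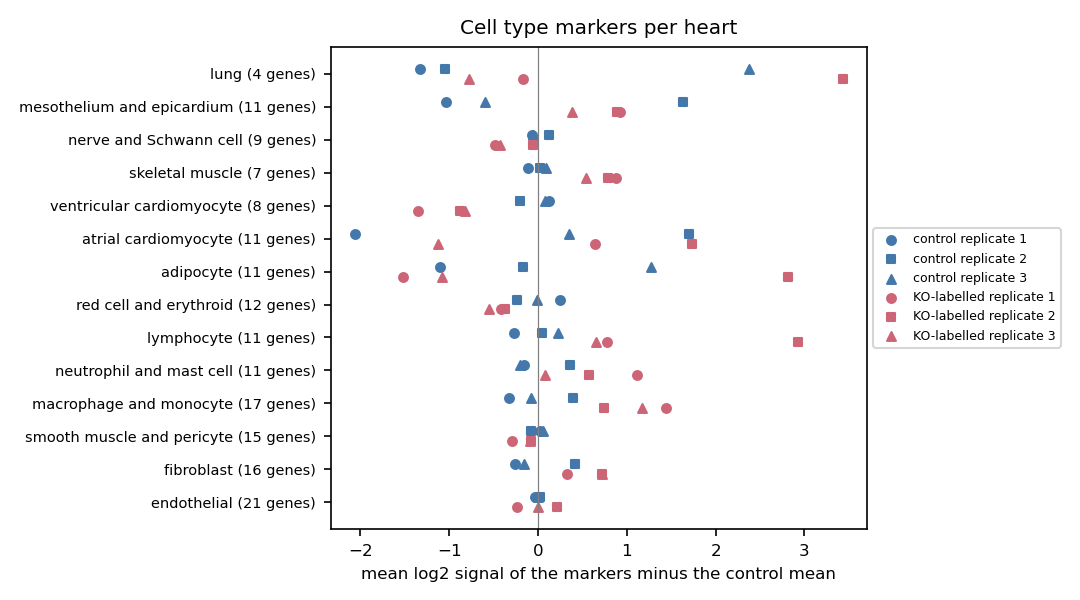
Mean log2 signal of each cell type's measured markers in each heart, as the difference from the mean of the 3 control hearts (horizontal axis), for 14 marker lists (vertical axis), with control hearts in blue and KO-labelled hearts in red. The 3 KO-labelled hearts lay at or below -0.83 for ventricular cardiomyocyte markers and at or above 0.74 for macrophage markers, while adipocyte and lung markers were high in control replicate 3 and KO-labelled replicate 2.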

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

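Spike-in scaling and array weights fitted gene by gene were chosen after the data were seen. With 7818 changed genes and features (3216 higher, 4602 lower) as reported, the totals were 4345 without a filter on dim probes (1912 and 2433), 13713 with array weights (5320 and 8393), whose fit gave a convergence warning, 12703 with array weights gene by gene (7880 lower), 4854 with the replicate block (2122 and 2732) and 5016 with a plain test per gene (2831 lower). Spike-in scaling gave 2437 lower. Correlations between hearts of the same replicate number, after removing group means, were -0.15, -0.13 and -0.10, which gave no sign of pairs. So few hearts cannot show whether the numbers mark a litter or day, which the labels do not say. Leaving out 1 heart gave 3962 to 8673 changed, 1894 to 3272 higher and 2068 to 5401 lower. Under the alternatives with a test, the direction of Egln1 (log2 difference -1.38 to -0.98), Egln3 (1.86 to 2.22) and Pln (-2.07 to -1.64) and their side of the threshold were kept in all. Egln2 passed with array weights (log2 difference -0.34) and with those gene by gene (-0.35), and under no other alternative run.

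The 22 called lists all missed the threshold in camera with an estimated correlation, which called 0 (2 at an unadjusted p of 0.05). Its adjusted p was 0.388 for other HIF targets, 0.472 for glycolysis, interferon, unfolded protein response, cell cycle and cell death, 0.507 for the fetal programme, 0.534 for matrix, 0.625 for lymphocytes and 0.623 for the other called lists. Fry missed fibroblast (adjusted p = 0.0914), macrophage (0.0515), lymphocyte (0.24), erythroid (0.0661), inflammation (0.103) and immediate early lists (0.115). It called thyroid receptor and nerve lists (0.0212), calcium handling (0.0163) and skeletal muscle (0.00677). Fry does not compare a list with other genes, and 39.0% of all genes and features passed. Its calls for change in either direction therefore say little about a single list. Fry for change in either direction called 35 lists, missed lymphocytes (0.197) and added 14: oxygen sensing (0.000223), T3-lowered (0.000341), skeletal muscle (0.000581), calcium, beta-adrenergic, nerve and angiogenesis (0.00124), smooth muscle (0.00233), heat shock (0.00302), antioxidant (0.00425), thyroid receptor and creatine (0.00488), clock (0.0113) and iron (0.0138).

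Without members shared by lists, T3-raised (adjusted p = 0.761), fibroblast (0.111) and erythroid lists (0.0872) missed the threshold. Calcium handling passed without a filter on dim probes (0.011) and with spike-in scaling (0.0228), which ended the fibroblast (0.0629), erythroid (0.0584) and immediate early calls (0.066). The erythroid list also missed it with normexp (0.0586), quantile (0.176) and loess scaling (0.0576), and lymphocytes with probes above background on all arrays (0.102), array weights (0.242) and those gene by gene (0.125). Mesothelium passed with both kinds of weights (0.0128 and 0.00643). Leaving out 1 heart gave an adjusted p of 0.0358 to 0.142 for calcium, 0.000249 to 0.0557 for fibroblasts, 6.13e-05 to 0.565 for mesothelium, 0.0196 to 0.121 for erythroid and 0.00112 to 0.0674 for immediate early genes. The cause of these changes was not tested. The direction of 29 results for lists turned, all in lists called neither as reported nor under that alternative. Their adjusted p was, for antioxidants, 0.917 and 0.94 with array weights and those gene by gene, 0.861 with normexp, 0.944 with quantile scaling and 0.989 with the replicate block; for beta-adrenergic signalling 0.935 with unshared members and 0.853 with normexp; for adipocytes 0.529 and 0.727 with the weights, 0.993 with loess, 0.999 with fry and 0.900 with spike-in scaling; for endothelium 0.756 with fry, 0.982 with unshared members and 0.977 without a filter on dim probes; for T3-lowered genes 0.993 with loess, 0.83 with fry and 0.966 without that filter; and for angiogenesis 0.408 with fry and 0.733 with unshared members. Leaving out 1 heart turned the direction of antioxidants (0.778 to 0.974), beta-adrenergic signalling (0.682 to 0.969), adipocytes (0.207 to 0.966), atrium (0.126 to 0.965) and endothelium (0.284 to 0.966). The median of 6 lists, none of them called, changed sign under another scaling. Lamp3, not called, turned to a log2 difference of 0.00555 with spike-in scaling (adjusted p = 0.979). Why these turned was not tested. Of the other results for lists 884 and for single genes 3327 kept direction and side of the threshold, while 156 for genes missed it and 34 newly passed. Dim signal limits genes near background: with normexp the log2 difference of Cdk1 was 0.31 in place of 2.65. The slide block could not be fitted because all arrays share 1 slide.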

Other observations

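The tests of the gene families, of spike-in scaling and of macrophage against endothelial markers were chosen after the result was seen. Among 158 gene families with at least 10 measured members, 23 passed camera with a preset correlation, 13 higher and 10 lower, and 0 passed with an estimated correlation, with 6 at an unadjusted p of 0.05. Families were formed by symbol stem. The stem H, which mixes histone, histocompatibility and a few other genes, had 39 of 71 higher and 4 lower (median log2 difference 0.89, adjusted p = 4.33e-10), and of 42 olfactory receptor genes 19 fell and 0 rose (median -0.75, adjusted p = 0.00284). Genes of the mitochondrial ribosome fell, 38 of 48 of its large subunit (median log2 difference -0.75, adjusted p = 6.65e-09) and 25 of 29 of its small subunit (median -0.69, adjusted p = 6.38e-07). So did 8 of 10 coenzyme Q synthesis genes, 10 of 14 genes of inner membrane protein import, 9 of 16 peroxisome assembly genes and 8 of 13 ankyrin repeat and SOCS box genes. Of 27 collagen genes 23 rose (median 1.58, adjusted p = 7.62e-11), and 10 of the 27 were also in the fixed lists. The adjusted p of each of these families was 0.82 with an estimated correlation, and their medians kept their signs under the 4 other scalings. The families were not tested under another background correction, which matters most for dim genes. How near background the olfactory receptor probes lay was not examined.

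The number of changed genes was weighed first. Of the 10 splits of the 6 hearts into 3 and 3, 1, the real one, gave as many changed genes (7818), the highest other split gave 0 in limma, and 10 splits are too few for a share under 0.05. A position or hybridisation effect differing widely between probes was argued against only for 7 E1A spike-in probes, which share 1 mix. They spread between the groups with an SD 0.0655 times that of genes (0.0561 against 0.858). That SD leaves out their common shift (mean log2 difference -0.24). Each group also lay in its own column of positions, so a contribution of position stays open. Scaling was also argued against as the whole cause, since the lowest count over 4 scalings was 6062, with the spike-ins, and the highest 8316. A difference in how the RNA of the groups was prepared was not tested, since spike-ins are added later, and a biological effect of the genotype stays open beside it.

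The Esr1 probe far above control in KO-labelled hearts was weighed next. The other 2 probes had no signal well above background on any array, so they may be dead, and neither the smallest rise over the 3 probes (0.16 on the log2 scale) nor the gap between the largest and the smallest (10.20) decides between explanations. Transcription of the whole endogenous gene stays open, as does a transgene that carries part of the Esr1 sequence, such as an inducible Cre fused to the receptor's ligand-binding part. The gene table lists a heart-specific transgene of that kind under A1cf, whose probe differed by 0.28 and was above background on 0 arrays of either group, which decides nothing because an inserted transgene need not change its host gene. The labels do not name the Cre, so a transgene stays a hypothesis.

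The fall of cardiomyocyte metabolic genes with the rise of matrix, macrophage and cell cycle genes was weighed last. A uniformly lower share of cardiomyocyte RNA would raise markers of all other cell types equally. Macrophage markers rose by 1.12 ± 0.39 (SE) more on the log2 scale than endothelial markers. This pair of lists was chosen after the values were seen and judged by its SE without a p. It therefore argued only weakly, and against that uniform case only. An uneven change in the shares of cell types, such as more macrophages or fibroblasts, stays open, as does a change in the macrophages themselves. The comparison cannot tell these from a fall within cardiomyocytes, and all 8 measured ventricular cardiomyocyte markers fell. Activity of Cre recombinase, which the controls lack, may contribute: the 27 measured p53 targets had a median log2 difference of 0.21, with 12 higher and 6 lower (list adjusted p = 0.105, adjusted p = 0.486 with an estimated correlation; 9 shared with other lists), which did not decide it. Without hearts that carry Cre and no floxed alleles, the effects of Cre or of an inducer cannot be told apart from those of the deleted genes. An effect of losing PHD2 and PHD3 on the heart stays open as the biological explanation.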
